A study of Mus musculus with 12 samples.

How the data were processed

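CUT&Tag, in which an antibody-tethered transposase cuts and tags the DNA beside a chromatin mark, was read in KPC1199, a cultured murine pancreatic ductal adenocarcinoma (PDAC) line. The marks were H3K4me3, which lies at active promoters, H3K27Ac, which lies at active promoters and enhancers, H3K27me3, the mark deposited by Polycomb repressive complex PRC2, and ubiquitinated histone H2A, the mark deposited by PRC1 and called H2A119Ub in the labels. Each of the 4 marks was read in 3 cell states: untreated cells without selection for PD-L1, cells given 10 ng/ml IFN-gamma without selection, and cells given IFN-gamma that were PD-L1 high. This made 12 libraries with 1 library per mark and cell state, so no comparison has a replicate check and no p-value is given.

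The deposited table holds a signal for each gene and library, normalised by the authors. Bowtie2 2.4.2, HOMER, MACS2 2.2.7.1 and the mm10 build are named per the submitters' processing notes, which state neither the role nor the order of these tools. The window placed on each gene, the removal of duplicate reads and the scaling are not given in the sources used here. Multiplied by 6000, the values of each library fell on whole multiples of a step set by that library, which was fitted as 0.5 tags, and 100% of the values lay within 10% of such a step. The value of 1 tag so found was 0.989 to 1.03 in 11 libraries and 1.32 in the H2A119Ub library of all IFN-gamma treated cells. The values were therefore read as tag densities over windows of 6000 bp and are given as normalised tags per window, a reading inferred from the values. Were each library scaled to 10 M tags, the depth would be 9.72 to 10.1 M tags in 11 libraries and 7.59 M in the H2A119Ub library of all IFN-gamma treated cells. The table has 25507 windows under 25450 gene names, of which 57 windows repeat a name. Symbols matched the RefSeq gene table of GRCm38.p6, the assembly known as mm10, for 25098 windows (98.4%), and gene coordinates come from that table. All value columns of the table were used.

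For each mark, a pseudocount equal to the 10th percentile of the values above 0 in its 3 libraries was added, and the log2 ratio of each contrast was centred on the median of the windows kept. Pseudocounts came to 1.99 tags for H3K4me3, 5.06 for H3K27Ac, 2.03 for H3K27me3 and 8.18 for H2A119Ub. Windows with a mean over the 3 libraries at or above the median window of the mark were kept. The count of windows at least 2-fold higher or lower described each contrast. Ratios are on the scale of the value plus the pseudocount, which understates differences at low windows. Intervals at 95% are exact Poisson intervals for levels and Clopper-Pearson intervals of the recovered tags for ratios, centred in the same way and without the pseudocount. They cover counting error only, and compare 2 libraries, not 2 conditions. CUT&Tag reads without molecular identifiers are not independent molecules, so these intervals are lower limits of the error. A window at 0 allows up to 3 tags. To give the count that counting noise alone makes, both libraries of a contrast were drawn 100 times from their pooled rate. For H3K27me3, the share of windows called in both contrasts against untreated cells, which share the untreated library, was set beside 100 draws in which the PD-L1 high and untreated libraries have their pooled rate, a test added after seeing the data.

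Before the data were examined, 22 gene lists were fixed: IFN-gamma signalling and transcription factors, GBP and IRG GTPases, MHC class I and antigen processing, MHC class II, immune checkpoint ligands and modulators, chemokines and cytokines, interferon-stimulated antiviral genes, PRC1 components, PRC2 components and H3K27 demethylases, Hox genes, developmental transcription factors, epithelial and ductal genes, mesenchymal and basal-like genes, acinar and endocrine pancreas genes, cell cycle genes, PDAC drivers and tumour suppressors, NF-kB targets, stemness genes, cell death genes, ribosomal protein and housekeeping genes, leukocyte markers, and fibroblast and endothelial markers. A list's median was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins, as a description of these libraries. For H3K27me3, random lists matched on the H3K4me3 level as well, in 10 bins within each bin of H3K27me3, were added after seeing the data. Members below the level filter were left out, and a gene with several windows took the one with the highest mean level. The genes named were also fixed by rule. In the contrasts of IFN-gamma over untreated and of PD-L1 high over all IFN-gamma treated cells, these are the 3 highest and the 3 lowest kept windows of each mark. Predicted genes, RIKEN clones, microRNAs, small nucleolar RNAs and symbols starting with LOC, AI, BC, AU or n-R were skipped. Added to them are Cd274, Pdcd1lg2, Irf1, Ciita, Nlrc5, B2m, H2-K1, Cxcl10, Socs1, Rnf2, Bmi1 and Ezh2, and the 2 members of a list with the largest absolute ratio. A further gene of the fixed set is not reported here. Genes outside this rule are said to be chosen after their values were seen.

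Alternatives were 0.25 and 4 times the pseudocount, no filter on low levels, a filter at the 75th percentile, no centring, quantile normalization of the 3 libraries of a mark, and the mean over all windows of a gene. A count of windows that also had a counting interval excluding 0 was added after seeing the data. The procedure was tested on simulated data with 200 changed windows drawn from the real levels of 25507 windows. For H3K4me3 after IFN-gamma, it called 54% of the 50 windows made 2-fold different and 100% of those made 3-fold, 4-fold or 8-fold different, with 0 unchanged windows called. For H3K27me3 in PD-L1 high over all IFN-gamma treated cells, the shares were 46%, 88%, 100% and 100%, with 115 unchanged windows called. The simulated libraries held counting noise only, so calls from spread or enrichment that differs between libraries were not tested. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.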

Results

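Gene windows were compared across the 12 libraries to ask how chromatin marks differ after IFN-gamma, a cytokine that induces PD-L1 and antigen presentation, and how PD-L1 high cells differ from all cells given IFN-gamma. The share of tags in gene windows, if each library was scaled to 10 M tags (M, 10 to the power of 6), was 71.0%, 84.6% and 88.3% for H3K4me3 in untreated, all IFN-gamma treated and PD-L1 high cells. It was 20.4%, 23.9% and 22.99% for H3K27Ac, 16.5%, 20.04% and 21.2% for H3K27me3, and 13.3%, 15.6% and 14.2% for H2A119Ub. Levels across windows correlated by mark, with Spearman rho from 0.906 to 0.981 between libraries of 1 mark. Between marks, rho was 0.912 to 0.931 for H3K4me3 with H3K27Ac, 0.638 to 0.771 for H3K27me3 with H2A119Ub, and 0.062 to 0.270 for H3K27Ac with H3K27me3. Neighbouring genes can share a window: of 2695 neighbouring pairs within 1000 bp of each other, 1363 (50.6%) had H3K4me3 totals within 5%.

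In the library of all IFN-gamma treated cells, H3K4me3 was higher than in untreated cells at the interferon-inducible GTPases, at PD-L1 itself and at genes of antigen presentation. Gbp6 (chromosome 5, 105270702 to 105295871, mm10), a guanylate-binding protein of cell-autonomous immunity, had 9.96 tags in untreated cells and 468.8 after IFN-gamma, a log2 ratio of 5.07 (95% interval 4.43 to 6.39). Gbp4, of the same family, had 10.95 and 473.3 tags (log2 4.97, 4.35 to 6.21), and Tgtp2, an immunity-related GTPase, had 13.94 and 440.5 (4.56, 3.99 to 5.63). Cd274, which encodes PD-L1 (chromosome 19, 29362107 to 29388095), had 229 and 650 tags (1.26, 1.05 to 1.49). Batf2, a transcription factor induced by interferon, had a ratio of 2.39 (2.001 to 2.90), above Irf1, another transcription factor of the interferon response, at 1.10 (0.96 to 1.24).

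Of 16 GBP and IRG GTPases above the H3K4me3 filter, 15 were at least 2-fold higher after IFN-gamma, with a median log2 ratio of 2.63 that lay above all 10000 random lists. Gbp and Tgtp genes are paralogs whose reads can be shared, so the value of a single member is uncertain. Among 19 genes of MHC class I and antigen processing, 4 were at least 2-fold higher and the median was 0.34, again above all random lists. Psmb8, a subunit of the immunoproteasome, was at 1.77 (1.57 to 2.003), and Tap1, the peptide transporter, at 1.31 (1.19 to 1.44), a window it shares with Psmb9. B2m, the light chain of MHC class I, was at 0.34 (0.20 to 0.47), and the heavy chain gene H2-K1 at 0.59 (0.44 to 0.75). Interferon-stimulated antiviral genes had a median of 0.45 over 22 members, with 4 at least 2-fold higher, led by Zbp1, a sensor of Z-form nucleic acids, at 2.16 (1.67 to 2.83) and Xaf1 at 1.72 (1.397 to 2.11). The list of IFN-gamma signalling had a median of 0.28 over 17 members and NF-kB targets one of 0.32 over 12, both above all random lists. Tnfaip3, an inhibitor of NF-kB, had 0.74 (0.55 to 0.93), Nfkbia 0.67 (0.47 to 0.88), and Socs1, a feedback inhibitor of cytokine signalling, 0.47 (0.36 to 0.59).

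The remaining medians of H3K4me3 outside the random 95% were small: 0.14 for immune checkpoint ligands (percentile 97.6), where Ceacam1 was at -0.68 (-0.92 to -0.45), 0.10 for chemokines and cytokines (97.9, but -0.26 without the level filter), with Il18 at -0.89 (-1.42 to -0.42) and Tnf at -0.71 (-1.22 to -0.23), and 0.32 for the 4 Hox genes above the filter (99.9, but -0.703 without it), with Hoxa5 at 0.47 (0.18 to 0.79) and Hoxa3 at -0.43 (-0.88 to 0.001). Of the genes encoding Polycomb subunits, Rnf2 was at 0.10 (-0.09 to 0.28), Bmi1 at 0.33 (0.12 to 0.53) and Ezh2 at 0.32 (0.17 to 0.47). H3K4me3 was lowest at Sectm1b, with 112.5 tags in untreated and 40.72 in IFN-gamma treated cells (-1.66, -2.25 to -1.17), Npy4r (-1.55, -2.003 to -1.17) and Lrtm2 (-1.53, -2.16 to -1.01). In all, 46 of 12754 kept windows were at least 2-fold higher and 131 at least 2-fold lower, against a mean of at most 0.04 from counting noise alone. The direction of this split depended on scaling: it was 66 higher and 23 lower without centring and 78 higher and 13 lower after quantile normalization.

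**Figure D1:**
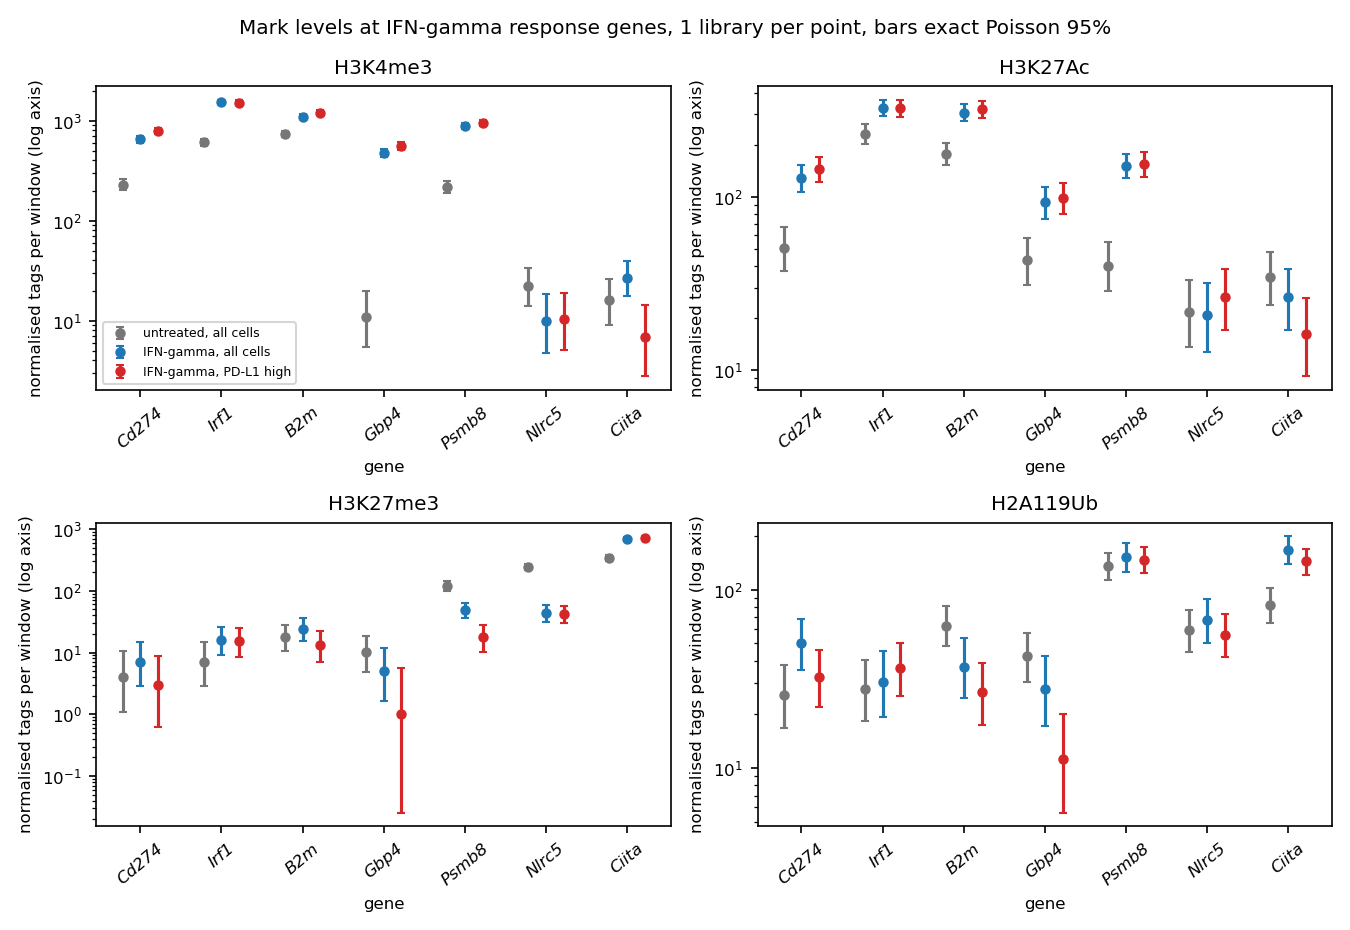
Normalised tags per window (log axis) at 7 genes in each mark. Each point is 1 library, coloured by cell state, and bars are exact Poisson 95% intervals; H3K4me3 at Cd274 stood at 229, 650 and 786 tags in untreated, all IFN-gamma treated and PD-L1 high cells, and H3K27me3 at Nlrc5 at 243, 43.1 and 42.3.

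H3K27Ac was also higher after IFN-gamma at interferon-inducible GTPases, though at fewer of them. Of 14 GBP and IRG GTPases above the filter, 8 were at least 2-fold higher, with a median of 1.27, above all random lists. Gbp6 and Gbp4, the highest in H3K4me3, were at 0.80 (0.42 to 1.29) and 0.79 (0.33 to 1.43). Gbp7 had 16.23 tags in untreated and 111.4 in IFN-gamma treated cells (2.21, 1.78 to 3.40), Tgtp1 27.39 and 151.9 (2.04, 1.63 to 2.88), and Gbp2 33.48 and 129.6 (1.57, 1.15 to 2.31). Cd274 had 50.7 and 129 tags (1.02, 0.62 to 1.61), and Cxcl10, a chemokine that attracts T cells, 40.6 and 128 (1.31, 0.90 to 1.97), while its H3K4me3 was below the filter and lower, at 63.7 and 49.7 tags (-0.58, -1.16 to -0.04). Psmb8 was at 1.56 (1.16 to 2.22), B2m at 0.53 (0.28 to 0.83), Irf1 at 0.25 (0.01 to 0.51), Socs1 at 0.31 (0.14 to 0.50) and H2-K1 at -0.16 (-0.64 to 0.33). Interferon-stimulated antiviral genes had a median of 0.18 (percentile 98.7), with Ifit3b at 1.31 (0.78 to 2.38) and Ifih1, an RNA sensor, at 1.197 (0.71 to 2.06).

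Acinar and endocrine pancreas genes had a median H3K27Ac ratio of -0.65, below all random lists, over 6 members that included the endocrine hormone gene Ppy at -0.77 (-1.36 to -0.29) and the acinar lipase gene Cel at -0.77 (-1.21 to -0.39). Random lists for H3K27Ac were matched on its own level only. The 1276 windows with the most H3K27me3 had a median H3K27Ac ratio of -0.47, with 17.5% above 0. Whether these pancreas genes differ beyond that fall was not tested. PRC1 components had a median of -0.20 (percentile 2.18), with Phc2 at -0.55 (-0.98 to -0.16) and L3mbtl2 at -0.47 (-0.91 to -0.07), and cell cycle genes one of -0.18 (0.48), with Aurkb at -0.60 (-0.95 to -0.28) and Cdc20 at -0.56 (-1.02 to -0.14). Without centring these 2 medians turned to 0.04 and 0.06. Among the Polycomb genes always named, Rnf2 was at -0.40 (-0.80 to -0.02) and Ezh2 at -0.23 (-0.63 to 0.18). The lowest H3K27Ac ratios stood at the cytokine genes Il27 (-1.79, -2.66 to -1.32) and Lta (-1.64, -2.54 to -1.14) and at Tle2, a corepressor (-1.64, -2.32 to -1.21). Of 12758 windows, 32 were at least 2-fold higher and 82 lower, which became 133 and 24 without centring and 92 and 54 after quantile normalization.

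H3K27me3 was lower after IFN-gamma at Nlrc5, the transactivator of MHC class I genes (chromosome 8, 94434335 to 94527272), and higher at Ciita, the transactivator of MHC class II genes (chromosome 16, 10480014 to 10531064). Nlrc5 had 243 tags in untreated and 43.1 in IFN-gamma treated cells (-2.66, -3.22 to -2.24), and was at -2.44 without centring and -2.88 after quantile normalization. Its H3K4me3 and H3K27Ac lay below the filter, at 22.4 and 9.93 tags of H3K4me3. Ciita had 340 and 692 tags of H3K27me3 (0.80, 0.61 to 0.999). Of 8 GBP and IRG GTPases above the filter, 3 were at least 2-fold lower, with a median of -0.49 (percentile 2.48, and 0.71 when random lists were matched on H3K4me3 as well). Igtp had 48.25 and 11.14 tags (-2.15, -3.43 to -1.37) and Gbp7 64.00 and 20.26 (-1.79, -2.68 to -1.13). Psmb8 was at -1.50 (-2.05 to -1.04) and Calr, a chaperone of MHC class I loading, at 1.06 (0.20 to 2.28) in a list whose median of -0.13 (0.09 without centring) lay within the range of random lists matched on level, and at percentile 0.09 of lists matched on H3K4me3 as well. H2-K1 was at -0.40 (-0.64 to -0.17), Cxcl10 at 0.17 (-0.36 to 0.73), Socs1 at 0.44 (-0.47 to 1.54), B2m at 0.19 (-0.72 to 1.21), Bmi1 at 0.28 (-0.44 to 1.07) and Rnf2 at -0.05 (-1.16 to 1.12), while Cd274, Irf1 and Ezh2 lay below the filter.

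At windows with low H3K27me3, this ratio rose with the H3K4me3 level (rho 0.48), so active promoters in general had higher values after IFN-gamma, and random lists matched on both levels were added after seeing the data. MHC class II genes had a median H3K27me3 ratio of 0.36 (percentile 99.8, and 99.7 with both levels matched), with 6 of 10 intervals above 0, H2-DMa at 0.56 (0.04 to 1.14) and Ctss, a protease of class II loading, at -0.72 (-1.83 to 0.24). PRC1 components had a median of 0.36 (99.4, but 75.2 with both matched), with Pcgf6 at 0.98 (0.07 to 2.28) and Cbx6 at 0.61 (-0.24 to 1.66). Ribosomal protein and housekeeping genes had one of 0.49 (99.5, but 87.2 with both matched), with Rpl19 at 1.51 (0.67 to 2.87) and Rps6 at 1.45 (0.63 to 2.73), at levels of only 10.2 and 11.2 tags in untreated cells. Mesenchymal and basal-like genes lay lower, with a median of -0.46 (0.98, and 0.40 with both matched), Krt5 at -0.80 (-1.62 to -0.08) and Krt17 at -0.68 (-1.31 to -0.10). Fibroblast and endothelial markers had -0.44 (0.70, but 6.10 with both matched), with Col1a1 at -0.81 (-1.53 to -0.17) and Acta2 at -0.68 (-1.36 to -0.05). The largest ratios rested on few tags in 1 of the libraries. Nanos1 had 2.03 and 33.43 tags (2.91, 1.85 to 6.93), Ist1 3.05 and 41.54 (2.88, 1.90 to 5.89) and Rbm42 3.05 and 33.43 (2.58, 1.56 to 5.59), while Olfr213 had 24.38 and 2.03 (-2.92, -6.93 to -1.80) and Tcp10a 26.41 and 3.04 (-2.71, -5.71 to -1.63). Counts were 484 higher and 575 lower of 12762 windows, against means of 60.5 and 59.4 from counting noise, with 907 and 286 without centring and 665 and 536 after quantile normalization. Of the 484, 64 (13.2%) were also 2-fold higher in PD-L1 high over untreated cells, and of the 575, 183 (31.8%) were also 2-fold lower. Draws with the same rate for the PD-L1 high and untreated libraries called a mean of 989 windows higher. Of these a mean of 63.7 (6.43%, highest 86) were also 2-fold higher in the second contrast. A mean of 281 were called lower, of which a mean of 6.76 (2.41%, highest 14) were also 2-fold lower. The numbers called differ from those observed, so neither the shares nor the counts compare directly. The draws also hold no trend with level, which PD-L1 high over untreated cells had. Its medians ran from -0.49 in the lowest 10% of kept windows to 0.74 in the highest 10%. The draws therefore cannot decide whether the overlap exceeds what the shared untreated library makes.

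H2A119Ub, as H3K27me3, was higher after IFN-gamma at Ciita, with 81.8 and 167 tags (0.73, 0.38 to 1.22). MHC class II genes had a median of 0.33 (percentile 98.8), with H2-DMb1 at 0.81 (0.51 to 1.21) and H2-Aa at 0.75 (0.31 to 1.48). PRC2 components had a median of 0.32 (98.2), with Rbbp4 at -0.50 (-1.17 to 0.07) and Ezh2 at 0.48 (-0.07 to 1.34), and developmental transcription factors one of 0.17 (99.7), with Dlx2 at 0.82 (0.44 to 1.41) and Tbx5 at -0.66 (-1.51 to -0.01). These lists were matched on the H2A119Ub level only. With H3K4me3 of untreated cells, H2A119Ub levels had a rho of 0.55 in untreated and 0.61 in all IFN-gamma treated cells. Whether the lists differ beyond such a trend was not tested. B2m was at -0.89 (-1.71 to -0.34), Nlrc5 at -0.08 (-0.63 to 0.51) and H2-K1 at 0.00 (-0.33 to 0.36), with Socs1 at 0.23 (-0.07 to 0.58) and Cxcl10 at 0.01 (-0.52 to 0.60). Cd274, Irf1, Rnf2 and Bmi1 lay below the filter. The highest windows were Dusp11 (1.69, 1.34 to 3.15), Sos1 (1.48, 1.11 to 2.41) and Slc10a7 (1.28, 0.88 to 2.203), and the lowest Dnase1 (-1.45, -2.39 to -0.97), Ccdc24 (-1.43, -2.10 to -1.04) and Cptp (-1.40, -2.52 to -0.87). Of 12754 windows, 52 were higher and 114 lower, and 249 and 28 without centring or 79 and 92 after quantile normalization. Of the 52, 3 were also 2-fold higher in PD-L1 high over untreated cells, and of the 114, 5 were also 2-fold lower, while 52 and 107 kept their sign with smaller ratios (medians 0.54 and -0.42). Both contrasts share the untreated library, which by itself favours the same sign, and no draws are given for the sign. The library of all IFN-gamma treated cells is the shallowest of this mark if scaled as above. Without centring, the median of the kept windows after IFN-gamma stood at 0.23 for H3K4me3, 0.24 for H3K27Ac, 0.22 for H3K27me3 and 0.24 for H2A119Ub, so the ratios above are relative to these shifts.

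Lists of other kinds stayed within the random range in all marks after IFN-gamma. Epithelial and ductal genes had medians of 0.05 for H3K4me3 (-0.02 after quantile normalization) and -0.16 for H3K27Ac (0.08 without centring), with the tight junction gene Cldn7 at -1.31 (-1.70 to -0.97) and the keratin gene Krt7 at -0.87 (-1.22 to -0.55) for H3K4me3. PDAC drivers and tumour suppressors had a median of 0.07 for H3K4me3, with Smad4 at 0.36 (0.16 to 0.57) and Arid1a at 0.32 (0.15 to 0.50). Cell death genes had one of 0.08, with Fas, a death receptor, at 0.88 (0.54 to 1.27) and Casp4, an inflammatory caspase, at 0.66 (0.27 to 1.10). Stemness genes had one of 0.07 (-0.02 after quantile normalization), with Cd24a at 0.30 (0.18 to 0.43) and Aldh1a3 at -0.26 (-0.51 to -0.01). For leukocyte markers, 2 of 22 passed the H3K4me3 filter, with Fcgr3 at -0.42 (-1.01 to 0.15) and Cd68 at 0.21 (0.00 to 0.43). Of 22 lists, 8, 5, 6 and 3 lay outside the random 95% for H3K4me3, H3K27Ac, H3K27me3 and H2A119Ub, where 1.1 would for lists of independent windows. Neighbouring members of a list can share a window, so 1.1 is not the exact number to compare with.

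**Figure D2:**
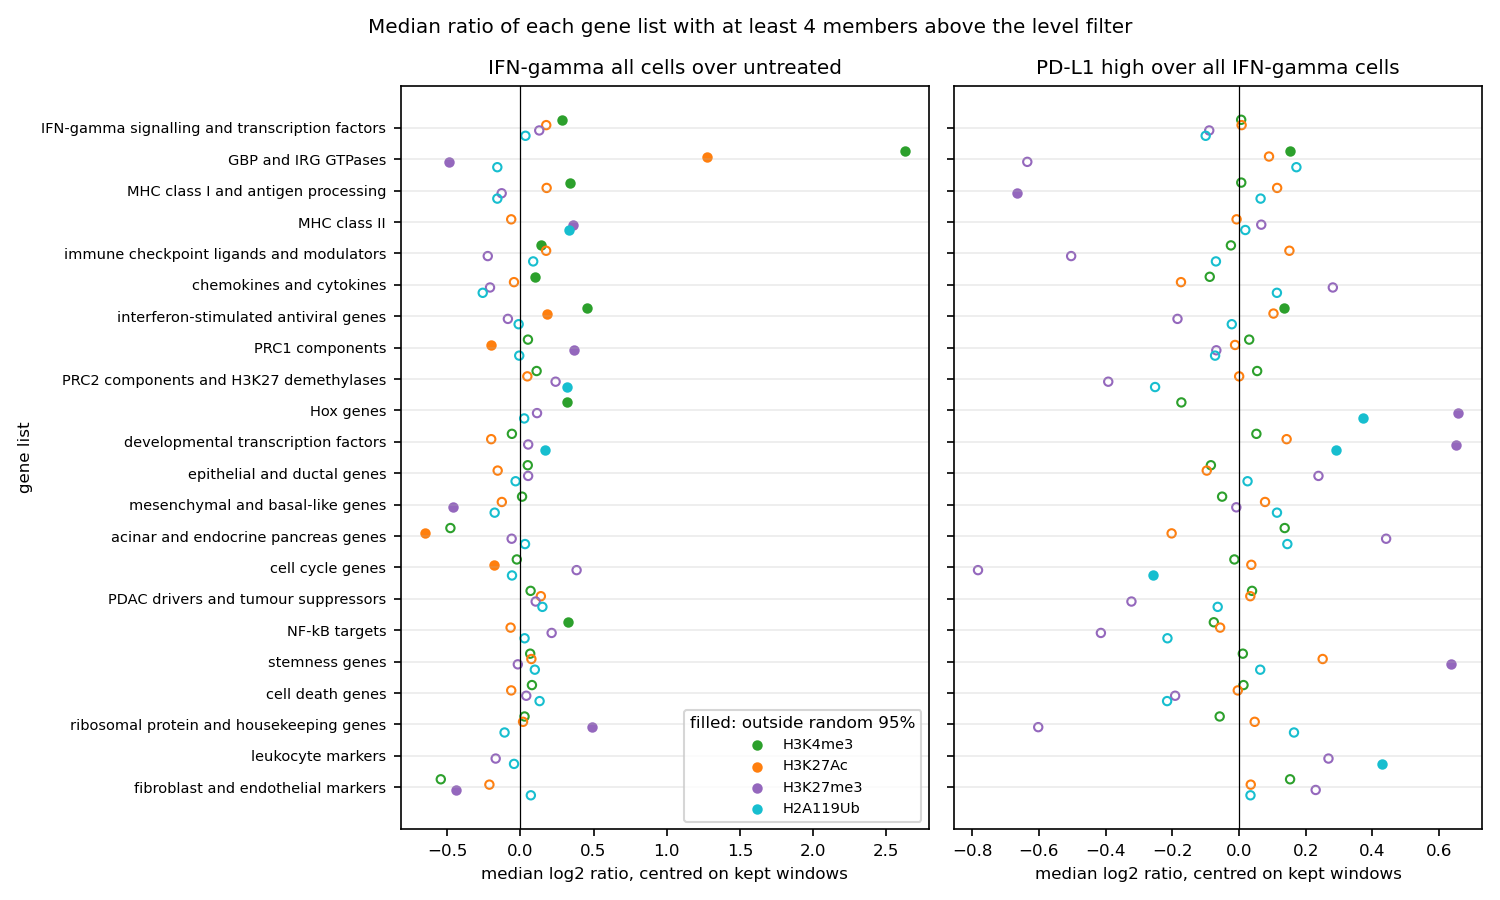
Median log2 ratio (horizontal axis, centred on the kept windows) of each gene list with at least 4 members above the filter, by mark, for IFN-gamma over untreated cells (left) and PD-L1 high over all IFN-gamma treated cells (right). Filled points lie outside the 95% range of random lists matched on the level of the mark alone; GBP and IRG GTPases stood at 2.63 for H3K4me3 on the left, and Hox genes at 0.66 for H3K27me3 on the right, which quantile normalization brought to 0.09.

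Across windows after IFN-gamma, H3K4me3 and H3K27Ac ratios correlated with a Spearman rho of 0.36 and a Pearson r of 0.39 over 11718 windows, the highest of 6 pairs of marks, where the others had a rho of 0.20 to 0.26. These are correlations across genes, which are not independent replicates, and 12 such relations were computed. Of 40 windows at least 2-fold higher in H3K4me3 and 28 in H3K27Ac, 11 were higher in both (0.0956 if independent). They were Cd274, Psmb8, Gbp2, Gbp5, Gbp7, Gbp10, Gbp11, Irgm2, Tgtp1, Tgtp2 and the predicted gene Gm12250. Where H3K4me3 was at least 2-fold higher, H3K27me3 was above its filter in 23 windows and lay below 0 in 20 of them, with a median of -0.63. In 6 of these 23 it was at least 2-fold lower (0.523 if independent): Gbp5, Gbp7, Igtp, Psmb8, Rtp4 and the transcript 9330175E14Rik. Gbp2 was an exception among the GTPases, at least 2-fold higher in both marks. Rtp4, an interferon-inducible chaperone singled out after its values were seen, had 13.9 and 311 tags of H3K4me3 and 80.3 and 42.6 of H3K27me3 (-1.10, -1.71 to -0.58).

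**Figure D3:**
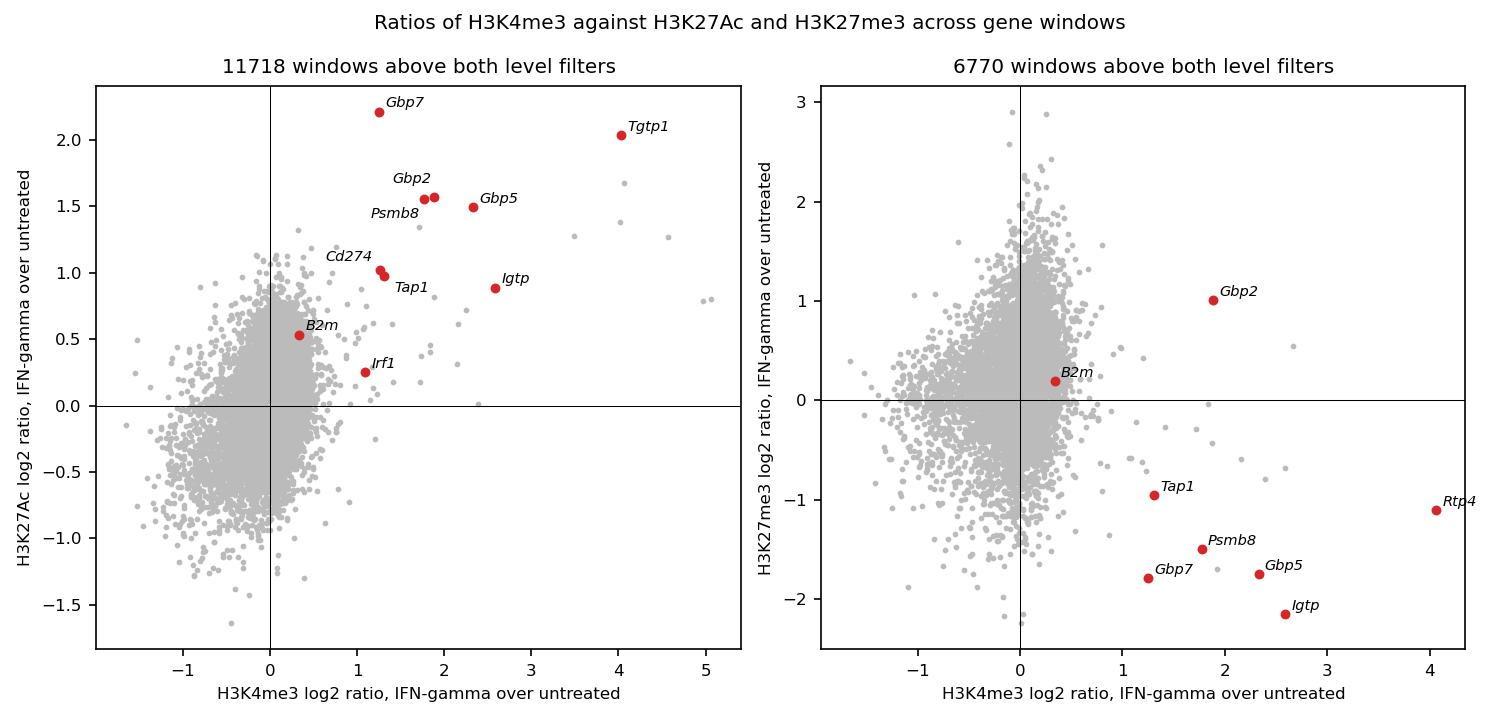
Log2 ratios of IFN-gamma over untreated cells for H3K4me3 (horizontal) against H3K27Ac (left) and H3K27me3 (right), 1 point per window above both filters, with response genes in red. Of 23 windows at least 2-fold higher in H3K4me3, 20 lay below 0 for H3K27me3.

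The libraries of PD-L1 high cells differed little from those of all IFN-gamma treated cells in H3K4me3 and H3K27Ac, and more in H3K27me3. The marks are not on an equal footing, with level filters of 57.6, 46.3 and 12.8 tags in this order. At windows with low H3K27me3, its ratio over untreated cells rose with H3K4me3 in all IFN-gamma treated cells (rho 0.48). In PD-L1 high cells that rho was -0.09, so part of the difference may lie in the library of all IFN-gamma treated cells. Cd274 had 786 tags of H3K4me3 in PD-L1 high and 650 in all IFN-gamma treated cells (0.20, 0.05 to 0.35), and 145 and 129 of H3K27Ac (0.22, -0.13 to 0.58). Casp12, an inflammatory caspase (chromosome 9, 5345442 to 5373034), had 218 and 89.4 tags of H3K4me3 (1.19, 0.85 to 1.58) and was the only kept window at least 2-fold higher in that mark. Its H3K27Ac, singled out after its values were seen, was at 116 and 53.7 tags (1.09, 0.68 to 1.66). Hox genes, which pattern the body axis, had a median H2A119Ub ratio of 0.37 and a median H3K27me3 ratio of 0.66. The top 5% of windows by H3K27me3 had 0.19 and 0.52.

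For H3K4me3 in this comparison, the GBP and IRG GTPases had a median of 0.15 (percentile 99.5, but -0.11 with the filter at the 75th percentile), with Gbp5 at 0.47 (0.26 to 0.69) and Gbp2 at 0.38 (0.21 to 0.55), and interferon-stimulated antiviral genes one of 0.13 (99.7), with Oasl1 at -0.54 (-0.85 to -0.25) and Ifit2 at 0.51 (0.21 to 0.83). Irf1 was at -0.09 (-0.19 to 0.01), B2m at 0.05 (-0.07 to 0.17), H2-K1 at -0.02 (-0.14 to 0.11), Socs1 at 0.01 (-0.09 to 0.10), Rnf2 at 0.25 (0.08 to 0.41), Bmi1 at -0.07 (-0.26 to 0.11) and Ezh2 at 0.05 (-0.08 to 0.18). After Casp12 came Pex7, a peroxisomal import receptor (0.94, 0.41 to 1.56), and the repeat RNA gene Rn4.5s (0.93, 0.48 to 1.43), whose copies make its reads uncertain. The lowest were Spats1 (-1.14, -1.87 to -0.55), Slc2a4rg-ps (-1.13, -1.75 to -0.61) and Acy3 (-1.05, -1.51 to -0.64). In total 1 window was higher and 10 lower, which became 3 and 4 without centring and 1 and 2 after quantile normalization.

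For H3K27Ac, no list lay outside the random range. The largest ratios were at Nup210l (1.26, 0.78 to 2.01), Naf1, a factor of telomerase assembly (1.19, 0.77 to 1.78), and Fjx1 (1.16, 0.64 to 1.96), and the lowest at Fam83c (-1.28, -2.12 to -0.78), Trnp1 (-1.27, -2.13 to -0.76) and Btbd17 (-1.25, -2.13 to -0.74). Irf1 was at 0.04 (-0.19 to 0.27), B2m at 0.11 (-0.12 to 0.35), Cxcl10 at -0.02 (-0.40 to 0.35) and Ezh2 at 0.38 (0.02 to 0.78), with H2-K1 at 0.40 (-0.02 to 0.87), Socs1 at -0.13 (-0.30 to 0.04) and Rnf2 at -0.25 (-0.69 to 0.16). Counts were 10 higher and 25 lower, or 6 and 36 without centring.

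H3K27me3 was higher in PD-L1 high cells at strongly marked windows in general, with 98.9% of the top 5% by H3K27me3 above 0, and developmental genes are among them. Of 39 Hox genes, 38 had an interval above 0, with Hoxa11 at 1255 tags in all IFN-gamma treated and 1933 in PD-L1 high cells (0.88, 0.78 to 0.99) and Hoxa7 at 0.87 (0.76 to 0.99), and the median of 0.66 lay at percentile 99.9, but within the random range (96.5, centred on 0.61) with H3K4me3 matched as well. Hox genes lie in clusters, so their windows are not separate observations. Random lists draw windows independently, so these percentiles can overstate how unusual the Hox median is. Developmental transcription factors had a median of 0.65, above all random lists (99.8 with both matched), with Tbx20 at 0.87 (0.72 to 1.01) and Pax9 at -0.94 (-2.46 to 0.08). Stemness genes had one of 0.63 (99.9, and 99.8 with both matched), with Abcg2 at 0.96 (-0.18 to 2.44) and Sox2 at 0.76 (0.63 to 0.89). Quantile normalization brought these medians to 0.09, 0.14 and 0.26, and the ratio rose with the level of the mark, from a median of -0.51 in the lowest 10% of kept windows to 0.52 in the highest 10%.

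Of 19 genes of MHC class I and antigen processing, 8 were at least 2-fold lower in H3K27me3 in PD-L1 high than in all IFN-gamma treated cells. Their median of -0.67 (percentile 0.09) was -0.55 after quantile normalization. This ratio fell with the H3K4me3 level at windows with low H3K27me3 (rho -0.54), and against random lists matched on H3K4me3 as well the median lay at percentile 7.42, within a random range centred on -0.42. Pdia3, a chaperone of class I loading, was at -1.45 (-2.81 to -0.60) and Tapbp, which encodes tapasin, at -1.27 (-2.64 to -0.39). Ciita was at 0.29 (0.14 to 0.45), Nlrc5 at 0.23 (-0.42 to 0.88, and -0.03 without centring), Cxcl10 at -0.56 (-1.20 to -0.002) and H2-K1 at -0.03 (-0.29 to 0.23). Ciita had 692 tags in all IFN-gamma treated and 709 in PD-L1 high cells. Groups of kept windows with median levels of 240 and 676 tags had median ratios of 0.34 and 0.52. Ciita was thus not raised beyond windows of like level. B2m was at -0.54 (-1.73 to 0.40), Socs1 at -0.04 (-0.996 to 0.84), Bmi1 at -0.02 (-0.76 to 0.68) and Rnf2 at 0.08 (-1.09 to 1.19). The lowest ratios stood at Casp9, the initiator caspase of the mitochondrial pathway (chromosome 4, 141793612 to 141815978), with 45.08 tags in all IFN-gamma treated and 1.01 in PD-L1 high cells (-3.69, -10.56 to -2.67), its neighbour Dnajc16 (-3.60, -10.46 to -2.57) and Ran (-3.11, -9.96 to -2.01), each resting on 1 tag in PD-L1 high cells. The highest were Olfr213 (2.06, 0.67 to 6.04), Bnc2 (2.05, 1.12 to 3.68) and Deup1 (1.87, 0.71 to 4.14). Of 12762 windows, 175 were higher and 1606 lower, against means of 91.0 and 85.8 from counting noise; the split was 63 and 2628 without centring and 429 and 668 after quantile normalization.

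**Figure D4:**
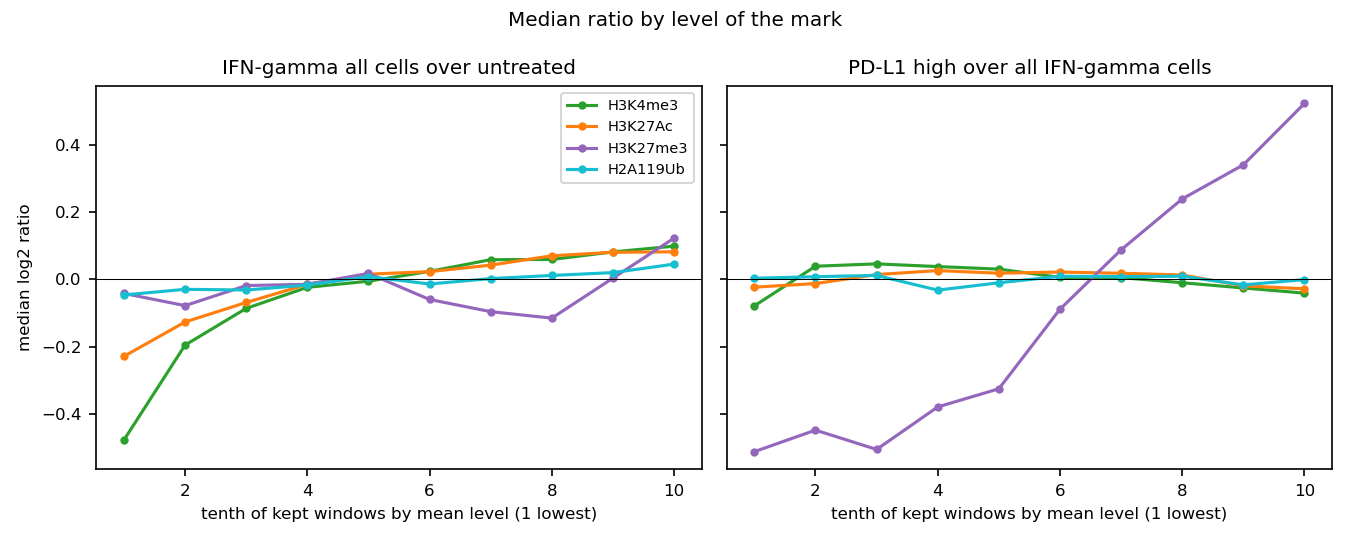
Median log2 ratio (vertical) in 10 equal groups of the kept windows by mean level of the mark (horizontal, 1 lowest), for IFN-gamma over untreated cells (left) and PD-L1 high over all IFN-gamma treated cells (right). H3K27me3 on the right went from -0.51 in the lowest to 0.52 in the highest group, and H3K4me3 on the left from -0.48 to 0.10.

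H2A119Ub was higher in PD-L1 high cells at the same Hox list, with 20 of 39 intervals above 0 and a median of 0.37 that lay above all random lists and was 0.38 after quantile normalization and 0.23 without centring. The limit from the clustering of Hox genes holds for this placement as well. Hoxd1 had 40.9 tags in all IFN-gamma treated and 79.7 in PD-L1 high cells (0.98, 0.49 to 1.75), and Hoxb2 89.0 and 149 (0.84, 0.46 to 1.32). Developmental transcription factors had a median of 0.29, above all random lists, with Tbx5 at 1.12 (0.61 to 2.01) and Nkx6-1 at 0.75 (0.30 to 1.34). Leukocyte markers had one of 0.43 (99.9, but -0.16 with the filter at the 75th percentile) over 13 members, with S100a8 at 1.03 (0.49 to 1.96) and Nkg7 at 0.73 (0.20 to 1.46). Cell cycle genes had one of -0.26 (0.86), with Ccnb1, a mitotic cyclin, at -1.01 (-1.83 to -0.57) and Mcm4 at -0.84 (-1.53 to -0.41). Random lists for this mark were matched on its own level, and not on H3K4me3 or H3K27me3. Among the 1276 windows with the most H3K27me3, the median H2A119Ub ratio was 0.19, with 75.6% above 0. With H3K4me3 of all IFN-gamma treated cells, H2A119Ub levels had a rho of 0.59 in that state and 0.49 in PD-L1 high cells. Whether these gene lists differ beyond such trends was not tested. The highest windows were Rn4.5s (1.95, 1.54 to 3.08), Fuca1 (1.48, 0.99 to 2.59) and Zar1 (1.29, 0.80 to 2.22), and the lowest Arhgap12 (-1.41, -2.60 to -0.99), Supt3 (-1.32, -2.34 to -0.90) and Arl5b (-1.31, -2.45 to -0.87). Ciita was at -0.07 (-0.43 to 0.28) and B2m at -0.24 (-1.16 to 0.49), with Ezh2 at -0.29 (-1.02 to 0.29), H2-K1 at 0.15 (-0.17 to 0.48), Cxcl10 at 0.14 (-0.39 to 0.68), Nlrc5 at -0.10 (-0.71 to 0.45) and Socs1 at -0.02 (-0.33 to 0.28). Of 12754 windows, 46 were higher and 66 lower, with 13 and 156 without centring. H3K27me3 and H2A119Ub ratios correlated across 9817 windows with a rho of 0.43 and an r of 0.40. Without centring, the median of the kept windows stood at -0.26 for H3K27me3 and -0.14 for H2A119Ub.

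Fibroblast and endothelial markers had medians of 0.15, 0.04, 0.23 (-0.03 without centring) and 0.03 for H3K4me3, H3K27Ac, H3K27me3 and H2A119Ub in PD-L1 high over all IFN-gamma treated cells, with Pdgfra at 0.69 (0.55 to 0.83) and Col1a2 at 0.63 (0.00 to 1.32) for H3K27me3. Leukocyte markers had 0.11, 0.12 and 0.27 for the first 3 marks. Of 22 lists, 2, 0, 4 and 4 lay outside the random 95% in the 4 marks.

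Against untreated cells, PD-L1 high cells had Cd274 at 1.46 (1.25 to 1.69) for H3K4me3 and 1.23 (0.84 to 1.81) for H3K27Ac, and Nlrc5 at -2.34 (-2.91 to -1.92) and Ciita at 1.18 (0.995 to 1.38) for H3K27me3. GBP and IRG GTPases had medians of 2.87 for H3K4me3, 1.32 for H3K27Ac and -1.15 for H3K27me3, and Hox genes 0.87 for H3K27me3 and 0.40 for H2A119Ub, where the top 5% of windows by H3K27me3 had 0.74 and 0.22. These ratios share libraries with both other contrasts and are no separate evidence for them. Pdcd1lg2, which encodes PD-L2, lay below the filter in all marks, with 11.5, 5.96 and 3.46 tags of H3K4me3 in untreated, all IFN-gamma treated and PD-L1 high cells.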

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

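All tests in this part were chosen after the result was seen. H3K27me3 at Dnajc16 (chromosome 4, 141761998 to 141790644), which encodes a J-domain protein, was the only named gene with 2-fold ratios of opposite sign against untreated cells. It had 11.2 tags in untreated, 42.0 in all IFN-gamma treated and 1.01 in PD-L1 high cells, so it was at 1.52 after IFN-gamma and at -1.99 in PD-L1 high cells, and at -3.60 between those 2 states. It was 1 of 11 windows at least 2-fold higher after IFN-gamma and 2-fold lower in PD-L1 high cells, where draws with 1 rate for the 3 libraries gave 0. The draws hold no spread between libraries and no trend with H3K4me3, so they show only that counting noise does not make such windows. Casp9, the neighbour of Dnajc16, had 18.3, 45.1 and 1.01 tags in the same states. Neighbouring genes can share a window, so these genes may not be separate observations. The difference between the states was not tested, since each state has 1 library.

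Dnajc16 belongs to the 1606 windows at least 2-fold lower in H3K27me3 in PD-L1 high than in all IFN-gamma treated cells. Quantile normalization left 668 such windows, 658 of them from the 1606, where counting noise gave at most 91. It removes only differences that follow the level of the mark, and the draws hold no spread between libraries. These counts therefore cannot decide whether a difference in enrichment over background between libraries is the whole cause. H3K27me3 tags at active promoters in the library of all IFN-gamma treated cells are a candidate explanation: over 6381 kept windows with low H3K27me3, the ratio had a Spearman rho of -0.54 with the H3K4me3 level, and 94.6% of the 1606 windows lay above the median of H3K4me3. The ratio of IFN-gamma over untreated cells had a rho of 0.48 with that level, and PD-L1 high over untreated cells one of -0.09. The median of PD-L1 high over untreated cells in the 1606 windows was -0.84. Draws with 1 rate for both libraries, which allow for the choice of windows on the PD-L1 high library, gave -0.28 (lowest -0.32). The draws hold no trend with level, while this ratio had a median of -0.49 in the lowest 10% of kept windows and 0.74 in the highest 10%. H3K27me3 lower in PD-L1 high cells than in both other states stays open, and these values cannot tell it from that trend.

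H3K4me3 was at least 2-fold lower after IFN-gamma in 131 windows. Quantile normalization left 13 windows, all among the 131, where counting noise gave at most 1. The draws hold no spread between libraries, so this cannot decide whether enrichment that differs between libraries is the whole cause. Such enrichment could account for the windows that quantile normalization removed. Of the 131, 98.5% lay in the lowest 20% of kept windows by level, which is consistent with windows near the floor of the filter. A loss of H3K4me3 at such windows in IFN-gamma treated cells was not tested separately and stays open.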

How the results depend on the processing

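All alternatives were set before the data were examined, except the count that also needs a counting interval excluding 0 and the random lists matched on H3K4me3, which were added after the result was seen. Counts below are of windows at least 2-fold higher and lower, first for IFN-gamma over untreated cells and then for PD-L1 high over all IFN-gamma treated cells, and the cause of a difference was not tested unless given. With 1 library per mark and cell state, no test of a condition and no paired analysis was possible because there are no replicates. Alternatives on peak sets were not run, as the table holds gene windows and no peaks. No filter on low levels adds windows of few tags, so counts grew by construction: H3K4me3 412 and 3245, then 535 and 1453; H3K27Ac 260 and 1136, then 520 and 419; H3K27me3 1804 and 2517, then 1245 and 3255; H2A119Ub 231 and 457, then 352 and 195. In the second contrast, rho between ratios was then 0.071 for H3K4me3 with H3K27Ac, -0.068 with H3K27me3 and -0.047 with H2A119Ub, and 0.28 for H3K27me3 with H2A119Ub. The H3K4me3 medians after IFN-gamma turned to -0.26 for chemokines and cytokines and -0.703 for Hox genes. A filter at the 75th percentile leaves fewer windows: H3K4me3 6 and 1, then 0 and 0; H3K27Ac 4 and 1, then 0 and 0; H3K27me3 71 and 69, then 4 and 417; H2A119Ub 8 and 29, then 8 and 14, with a rho of 0.20 for H3K4me3 with H2A119Ub in the second contrast. In that contrast it turned the medians of GBP and IRG GTPases for H3K4me3 to -0.11 and of leukocyte markers for H2A119Ub to -0.16. Quantile normalization gave H3K4me3 78 and 13, then 2 lower; H3K27Ac 92 and 54, then 6 and 10; H3K27me3 429 and 668 in the second contrast; and H2A119Ub 79 higher in the first. Without centring, H3K4me3 had 23 lower, then 3 and 4; H3K27Ac 133 and 24, then 6 higher; H3K27me3 907 and 286, then 63 and 2628; H2A119Ub 249 and 28, then 13 and 156. PRC1 components and cell cycle genes turned to 0.039 and 0.061 for H3K27Ac after IFN-gamma. With 4 times the pseudocount, H3K27Ac had 10 and 32, then 0 and 0; H3K27me3 204 and 264, then 67 and 776; H2A119Ub 2 and 10, then 2 and 0; and H3K4me3 4 lower in the second contrast. With 0.25 times it, H2A119Ub had 116 higher, then 91 and 116, and H3K27Ac 20 and 39 in the second contrast. The interval-based counts for H3K27me3 were 481 and 557, then 154 and 1544. Of the list medians under all settings, 289 moved by more than the spread of random lists and 925 did not, and of the ratios of named genes, 37 moved out of their counting interval and 692 did not. A further 6 medians outside the random range changed sign, and 0 ratios of at least 2-fold did; smaller values that crossed 0 are not among these 6.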

Other observations

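All tests in this part were chosen after the result was seen. A run of 22 genes on chromosome 5 from Cdk6, which encodes a cyclin-dependent kinase, to Steap1 had 16 genes with H3K4me3 above the genome-wide median of marked windows (538 tags), with 8690 at Cdk6 and 4317 at Fzd1, a Wnt receptor gene. Over the 19 marked genes of the run, the median was 3.31 times that of the genome for H3K4me3, 3.16 for H3K27Ac, 2.09 for H2A119Ub and 1.34 for H3K27me3, and of 12284 runs of as many marked genes, 2, 5, 1012 and 3677 were as high. A gain of DNA copies and strong promoters without one cannot be told apart: copies need all 4 marks high and promoters need H3K27me3 near that of other marked windows, and 1.34 lies between the bounds of 1.2 and 1.5 set for both. By library that value varied, at 1.43 in untreated, 1.499 in all IFN-gamma treated and 1.11 in PD-L1 high cells. The interval was picked for its high H3K4me3.

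At 6 neighbouring genes on chromosome 14 from 69241848 to 69695834 (Slc25a37, Synb, Gm16677, Entpd4, Entpd4b and Loxl2), the value was 0 in all 12 libraries. The table has 16 such runs of at least 4 neighbouring genes, most of them multi-copy families, and whether reads there were not unique or the DNA is lost was not tested. Of 65 genes on the Y chromosome, 60 were at 0 in all libraries, with 21 tags over the chromosome in total. In all, 360 windows of the table were at 0 in each library.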
